A study of Schizosaccharomyces pombe with 9 samples.

How the data were processed

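RNA was measured in 9 libraries of Schizosaccharomyces pombe, 3 each of wild type, tra1D and tra1-AA. Per the labels, cells in mid-log phase in YES medium were extracted with TRIzol, treated with DNase and poly(A)-selected, and stranded TruSeq libraries were read as single reads of 50 bases in a single lane of a HiSeq instrument. Per the submitters' processing notes, the authors demultiplexed the reads with bcl2fastq, aligned them with HISAT2 2.1.0 and counted them with HTSeq 0.9.1, and the deposited count table gives the read count per gene without normalisation. The authors' deposited comparison tables, made with DESeq2 1.18.1, give a log2 fold change and its log2 standard error for each mutant against WT. The deposited tables also give the Wald score of each gene, computed by the authors with DESeq2. The p-value and adjusted p-value of each gene were likewise computed by the authors with DESeq2 and deposited in these tables. Their base mean and the logarithm of the adjusted p given for tra1D were not used here. The genome build, the annotation and the strand setting of the counting are not given in the sources used here, so no coordinates are printed.

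The analysis started from the deposited counts. The table holds 5129 genes, of which 66 had no count in any library. Gene names and biotypes were taken from a reference annotation, in which 5114 IDs were matched (5111 by locus tag and 3 by an older ID) and 15 were not, with 5109 protein-coding genes among those matched. Per-sample columns left unused numbered 0. All 11 mitochondrial genes in the table lacked counts. Groups followed the titles of the samples. Library totals lay between 5738138 and 8101004 counts. Replicates were not copies of each other, since the chi-square per degree of freedom between them was 8.49 to 29.09.

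Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 4913 and set aside 150 with a count. A single edgeR 4.0.16 quasi-likelihood fit (R 4.3.3) of the 9 libraries with TMM factors gave the 3 comparisons, each adjusted by Benjamini-Hochberg at 0.05. The common biological coefficient of variation was 0.0932. Levels are CPM, counts scaled by edgeR to a common library size, with the SD over 3 replicates. For genes with few counts, the ratio of summed counts was given with an exact 95% interval, and 3 counts served as the upper limit for a count of 0.

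Gene lists, 31 in number, were fixed before the data were examined, with 569 names, of which 40 were not found. Names were matched by symbol or synonym, so a list can hold a gene of another function. Some genes are in several lists, so the list results are not independent. Among them are abc3 and str3 (iron and drug lists), csk1 (phosphate and MBF lists) and gst2 (stress response and Pap1 lists). The 27 lists with at least 5 tested members were tested by camera (limma 3.58.1) on log2 CPM with prior count 2 and a preset correlation of 0.01, adjusted over 81 tests, and again with the correlation estimated from the data. The results of 1 tested list are not reported here, though they are counted in the totals of tested and called lists. Of the 4 others, the P-cell list had 3 tested members, the Tf2 list 1 and the mitochondrial genome list none. The list of structural RNAs matched 4 protein-coding names and so says nothing of RNA quality. Tf2-11, the tested Tf2 member, had a log2 fold change of -1.35 in tra1-AA (edgeR, BH-adjusted p = 0.198) and -0.03 in tra1D, and both values are uncertain because a copy covers its whole coding sequence (100%). Named genes are the 8 largest changes in each direction among called protein-coding genes with non-overlapping group ranges and a mean of at least 10 CPM, up to 4 called members per list, and up to 3 per direction shared by the mutants; exceptions are stated where they occur.

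The agreement of the mutants was set against 50 simulations of unchanged groups sharing the same controls. Near-identical copies were sought with BLAST 2.17.0 (at least 50 bases and 98% identity, over at least 10% of the coding sequence). Runs of neighbouring genes and matched lists used 10000 random placements or lists, in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Chromosome ends were the 50 outermost genes at each of 6 ends. Figures were drawn with matplotlib 3.10.9.

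The fit was tested on simulated data with planted changes among 4904 genes. Changes of 1.5-fold were recovered in 85.1% (tra1-AA vs WT), 83.6% (tra1D vs WT) and 86.6% (tra1-AA vs tra1D) of genes, 2-fold changes in 95.5%, 100% and 98.5%, and 4-fold changes in 100%. False calls made up 5.1%, 2.6% and 4.5% of the calls. The simulated counts were drawn independently for each gene, and no planted change was below 1.5-fold. The median called change in the real data was 1.33-fold in tra1-AA and 1.37-fold in tra1D. These shares therefore do not describe the smaller real calls.

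Alternatives were DESeq2 1.42.0, limma-voom, RLE factors, library totals alone, no filter, a filter of 10 CPM in 3 libraries, fits of only 2 groups, protein-coding genes only, the replicate number as a block, each library left out in turn, an adjusted p of 0.01, and a test against a log2 change of 0.5. Leaving out WT replicate 3 and tra1D replicate 1 together was added after the data were seen. Titles share replicate numbers across groups but name no pairing. The fit was therefore planned without the numbers as a block. As a check of pairing, correlations of residual log2 CPM between libraries of the same number ran from -0.203 to 0.357.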

Results

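Poly(A)-selected RNA of the fission yeast Schizosaccharomyces pombe was sequenced from 9 libraries of 3 genotypes, with 3 replicates each. The genotypes were wild type (WT), a deletion of tra1 (tra1D) and a strain carrying a tra1 allele named tra1-AA, whose sequence change the labels do not describe. tra1 encodes a pseudokinase of the phosphatidylinositol 3-kinase-related (PIKK) family that is a subunit of SAGA, a transcriptional co-activator complex. Its paralog, tra2, serves another complex, NuA4. The series concerns TTT, a cochaperone of the chaperone Hsp90, and the maturation of PIKK proteins. The cultures were grown to mid-log phase in the rich medium YES. The depth, as the sum of counts over genes, was 8101004, 7913303 and 6208529 in WT replicates 1 to 3, 7068449, 7295107 and 5738138 in tra1D, and 6632838, 7254711 and 6819600 in tra1-AA. At this depth a single count was worth 0.123 to 0.174 CPM (counts scaled to a common library size), and a gene with no count in a library can have had up to 0.37 to 0.523 CPM there (3 counts). Counting intervals and these floors cover counting error only. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these samples.

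The libraries separated first by genotype against WT. The first principal component of log2 CPM held 51.8% of the variance and placed the WT libraries at -16.5, -16.8 and -18.4, the tra1D libraries at 4.93, 10.7 and 7.51, and the tra1-AA libraries at 8.36, 9.83 and 10.45. The second component held 12.6%: tra1D lay at 4.35, 2.16 and 7.10 and tra1-AA lower, at -4.73, 0.17 and -8.40, but the WT libraries spread over both, at 1.92, 7.62 and -10.2. Correlations of log2 CPM across genes were 0.987 to 0.993 between tra1D and tra1-AA libraries and 0.968 to 0.981 between WT and mutant libraries. The 10 genes with the most counts took between 6.9% and 8.7% of each library.

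The tra1 transcript (SPBP16F5.03c) was nearly absent from tra1D, as its labels require. It had 771, 704 and 561 counts in WT replicates 1 to 3, 5, 2 and 2 counts in tra1D, and 608, 570 and 470 counts in tra1-AA. The normalised level was 94.1 ± 4.55 CPM in WT, 0.440 ± 0.251 CPM in tra1D and 79.1 ± 8.22 CPM in tra1-AA (mean ± SD, n = 3). In tra1D it fell with a log2 fold change of -7.69 (SE 0.20, edgeR quasi-likelihood test, BH-adjusted p = 4.24e-10), and the normalised ratio of 2036 counts in WT to 9 in tra1D was 216 (95% counting interval 113 to 473). In tra1-AA its log2 fold change against WT was -0.25 (SE 0.10), which did not pass (edgeR, BH-adjusted p = 0.0998). This change of the tra1 transcript, tra1-AA vs WT, was -0.32 without tra1-AA replicate 1 and passed (edgeR, BH-adjusted p = 0.0454).

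**Figure D1:**
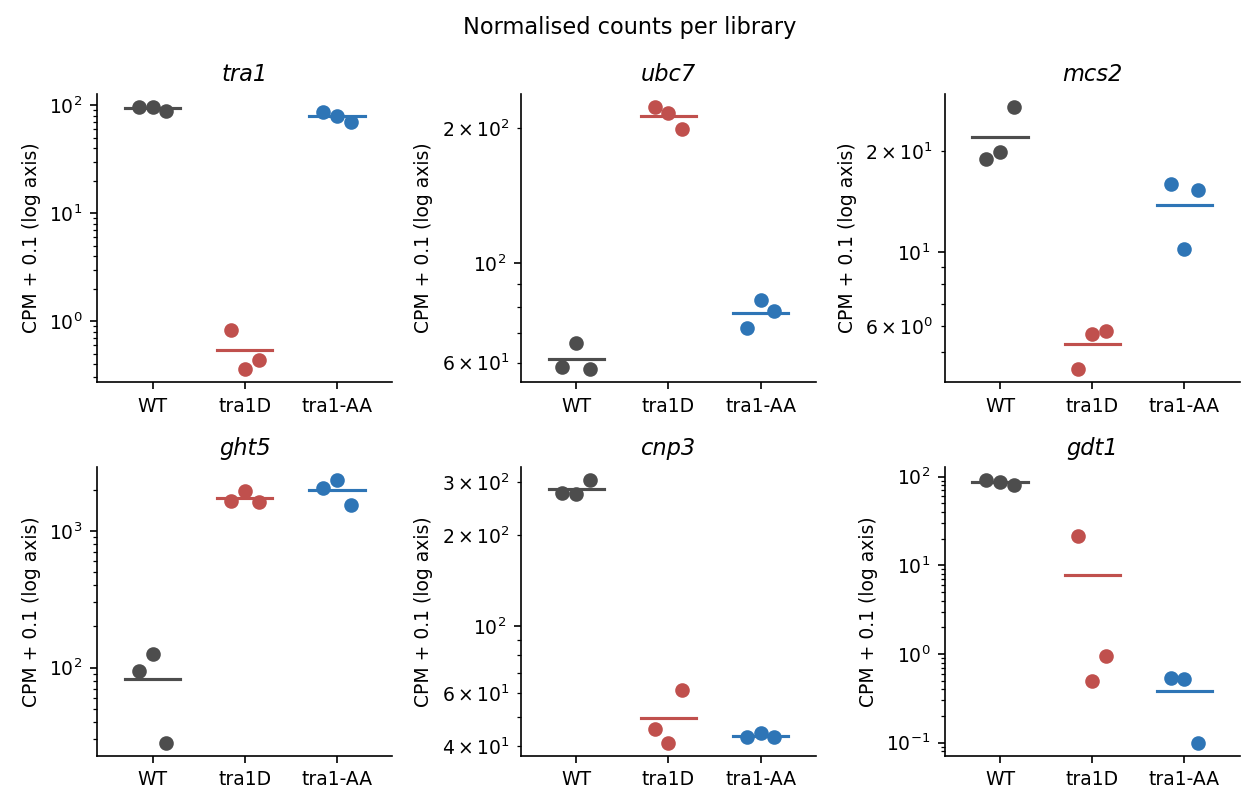
Normalised counts per library (CPM + 0.1, log axis) of tra1, its neighbours ubc7 and mcs2, and ght5, cnp3 and gdt1 in WT, tra1D and tra1-AA, with each point a library and each line a group mean. The points of tra1D and tra1-AA lie together for ght5 and cnp3 and apart for tra1 and ubc7, and tra1D replicate 1 has the highest gdt1 level of the mutant libraries.

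The comparison of tra1-AA with WT asks which transcripts differ in cells that carry the allele. ght5 (SPCC1235.14), a hexose transporter gene, rose 23.9-fold, from 82.5 ± 49.5 CPM in WT to 1978 ± 411 CPM in tra1-AA (SD, n = 3; log2 fold change 4.58, SE 0.41, edgeR, BH-adjusted p = 3.58e-05). Other single genes among the largest rises were gal10, encoding UDP-glucose 4-epimerase, with 4.13-fold, gal7, encoding galactose-1-phosphate uridylyltransferase, with 3.60-fold, and the aldehyde dehydrogenase gene atd1 with 5.04-fold. pho842, a gene of the phosphate transporter family, rose 5.11-fold from 116 ± 29.0 to 592 ± 62.9 CPM. In the other direction cnp3, which encodes the centromere protein CENP-C, fell from 284 ± 17.1 to 43.3 ± 0.903 CPM, and the flocculin gene pfl3 fell 3.85-fold (log2 fold change -1.94, SE 0.09).

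In all, 781 of 4913 tested genes changed in tra1-AA (edgeR quasi-likelihood test, BH-adjusted p under 0.05), of which 390 rose and 391 fell. The median absolute log2 fold change among them was 0.41, or 1.33-fold, and changes of at least 2-fold were found in 23 rises and 75 falls. The 8 largest rises by the rule for named genes were ght5, pho842, atd1, SPAC27D7.11c, gal10, gnr1, gal7 and gcd1, with log2 fold changes from 4.58 down to 1.60. The 8 largest falls were gdt1 (SPAC186.05c), nrg1, SPBPB10D8.02c, SPBC23G7.10c, SPAPB24D3.07c, grt1, SPBPB10D8.01 and cao2, with log2 fold changes from -8.14 to -2.73. The fitted fall of gdt1 rests on 1871 counts in WT against 6 in tra1-AA, a normalised ratio of 301 (95% counting interval 138 to 820). SPAPB24D3.07c fell from 496 ± 161 to 60.2 ± 18.4 CPM, and SPBPB10D8.01 from 121 ± 19.9 to 15.8 ± 3.68 CPM. cao2 varied in WT (51.6 ± 33.0 CPM), and with a library left out its fall ran from -3.39 (without tra1-AA replicate 2) to -2.21.

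Of the gene lists, the subtelomeric genes fell furthest in tra1-AA. Of 39 tested members 23 fell, 2 rose and 14 did not pass, with 25 falls and 2 rises adjusted over the list alone. The median log2 fold change was -1.31 (camera, BH-adjusted p = 1.34e-09; adjusted p = 0.401 with an estimated correlation). SPAC750.01 had 155 counts in WT and 2 in tra1-AA, a ratio of 74.7 (95% counting interval 20.3 to 622). SPAC186.06 and SPAC186.04c had no counts in tra1-AA against 70 and 67 in WT, and the lower 95% counting limits of their WT to tra1-AA ratios were 17.8 and 17. With these members set to a floor of 3 counts over the group the list median was again -1.31. That outcome was fixed beforehand, since at the floor they still lay 22.5-fold and 21.5-fold below WT, far under the median. A near-identical copy covers at least 10% of the coding sequence in 5 of the list's members, whose values are uncertain.

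The lists of flocculins, drug transporters and iron uptake genes were also lower in tra1-AA. Among 14 flocculin and agglutinin genes 3 fell and 11 did not pass, with 4 falls adjusted over the list alone (camera, BH-adjusted p = 0.0268; adjusted p = 0.401 with an estimated correlation); pfl3 and pfl7 had log2 fold changes of -1.94 and -1.19. That call was lost without WT replicate 3 or tra1-AA replicate 1 (camera, BH-adjusted p up to 0.0944). Of 16 genes in the drug and multidrug transporter list 4 fell, with 6 falls adjusted over the list alone (camera, BH-adjusted p = 0.00204, or 0.401 with an estimated correlation). The 4 were car1 with -1.46, abc3 with -0.64, bfr1 with -0.58 and caf5 with -0.42. car1 (SPBP26C9.02c) is an arginase gene that entered by its name, so the list result is not of transporters alone. abc3 is also in the iron list, and bfr1 and caf5 are also in the Pap1 list. Of 15 iron and siderophore uptake genes 5 fell, with 8 falls adjusted over the list alone (camera, BH-adjusted p = 0.0116; adjusted p = 0.402 with an estimated correlation). The siderophore transporter gene str1 had the largest of these changes, -2.13, which was -1.22 without WT replicate 3. The call of str1, tra1-AA vs WT, was lost without tra1-AA replicate 2 (-1.91) or tra1-AA replicate 3 (-2.08).

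Growth-related lists shifted by small amounts. Among 139 ribosomal protein genes 3 fell, 136 did not pass and 1 fell adjusted over the list alone, while 133 had a log2 fold change below 0 and the median was -0.13 (camera, BH-adjusted p = 4.42e-05; adjusted p = 0.763 with an estimated correlation). rpl102 fell from 799 ± 7.81 to 457 ± 4.31 CPM, and 6 members share sequence with a near-identical copy. Of 68 ribosome biogenesis genes 7 fell and 1 rose, with 5 falls and 1 rise adjusted over the list alone (camera, BH-adjusted p = 0.00352; adjusted p = 0.753 with an estimated correlation). The ribosomal protein call was lost without tra1-AA replicate 1 (camera, BH-adjusted p = 0.358), and the ribosome biogenesis call without WT replicate 3 or tra1-AA replicate 1 (up to 0.388). Of 59 amino acid biosynthesis genes 10 fell and 1 rose, the same counts as adjusted over the list alone (camera, BH-adjusted p = 0.00393; adjusted p = 0.643 with an estimated correlation), with met17 at -0.94, cys2 at -0.60 and arg4 at -0.39. That call was lost without tra1-AA replicate 1 (camera, BH-adjusted p = 0.0764).

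The proteasome and SAGA lists rose in tra1-AA. Of 37 proteasome genes 12 rose and 1 fell, with 14 rises and 1 fall adjusted over the list alone (camera, BH-adjusted p = 0.000186; adjusted p = 0.402 with an estimated correlation). rpn1301 rose from 78.6 ± 2.29 to 115 ± 4.18 CPM and rpn3 from 231 ± 9.66 to 296 ± 9.31 CPM, and the member that fell, rpn502, is uncertain because a copy covers its whole coding sequence (100%). The call of rpn502, tra1-AA vs WT, was also lost without WT replicate 1 (-0.39) or WT replicate 2 (-0.33). Of 19 SAGA subunit genes, tra1 included, 6 rose and 13 did not pass, with 7 rises adjusted over the list alone (camera, BH-adjusted p = 0.00687; adjusted p = 0.401 with an estimated correlation). taf6 had a log2 fold change of 0.33 and ada2 of 0.41. The call of taf6, tra1-AA vs WT, was lost without WT replicate 1 (0.28) or tra1-AA replicate 2 (0.29). That of ada2, tra1-AA vs WT, was lost without WT replicate 1 (0.36), tra1-AA replicate 2 (0.40) or tra1-AA replicate 3 (0.37).

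The following lists held changed genes in tra1-AA without passing as groups in camera (BH-adjusted p of 0.0563 and above). In the stress response list 6 of 23 genes rose and 7 fell (7 and 8 adjusted over the list alone): the metallothionein gene zym1 rose 2.96-fold, and gst2 (glutathione S-transferase) and rds1 fell 4.86-fold and 4.17-fold. Among 19 Pap1-dependent oxidative stress genes 4 rose and 7 fell, also adjusted over the list alone, with the thioredoxin peroxidase gene tpx1 at 0.66 and obr1 at -2.20. Of 23 glucose-repressed and hexose transporter genes 6 rose and 3 fell (7 and 5 adjusted over the list alone), including the invertase gene inv1 at 1.94 and the alpha-glucosidase gene agl1 at -1.12. Of 31 mating and sexual differentiation genes 5 rose and 2 fell (8 and 3 adjusted over the list alone), with ste11, the transcription factor of sexual differentiation, at 0.85 and pac2 at -0.81. Of 19 Hsp90 and heat shock chaperone genes 4 rose and 2 fell (5 and 3 adjusted over the list alone), with the Hsp90 cochaperone gene sti1 at 0.44; the median and mean of this list were -0.06 and -0.05 while camera's direction was up. Of 24 nitrogen and amino acid transport genes 3 rose and 2 fell (5 and 4 adjusted over the list alone), with put1 at 0.92 and cat1 at -0.95, and a median of -0.05 against a mean of 0.02. Of 21 MBF and S phase genes 4 fell (5 falls and 1 rise adjusted over the list alone), with the kinase gene mik1 at -0.76.

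In the NuA4 list 2 of 16 genes rose in tra1-AA, vid21 and arp42 (SPAC23D3.09). arp42 entered through a synonym and belongs to other complexes, SWI/SNF and RSC. Smaller counts of changed genes were also found in tra1-AA among PIKKs with TTT and R2TP (1 of 11 rose) and phosphate acquisition (1 rose and 1 fell of 10). Copper and zinc homeostasis (1 rose and 3 fell of 11) and thiamine-regulated genes (1 of 8 fell) had few calls too. So did sterol and low-oxygen genes (2 of 28 fell) and the nuclear respiratory chain (2 rose and 1 fell of 42). Among 7 M-cell genes 1 rose, while none of 3 P-cell genes or 11 histone genes passed in edgeR. Of 10 genes used as strain markers, arg3 fell with a log2 fold change of -0.38. The median and mean differed in sign for strain markers (0.03 and -0.003) and for copper and zinc (-0.16 and 0.004), and for phosphate camera's direction was down with a median of 0.04. Adjusted over the list alone, the NuA4 list had 1 rise (arp42), phosphate acquisition 1 rise and 1 fall, and copper and zinc 1 rise and 3 falls. The thiamine list then had 2 falls, and sterol genes and strain markers 1 fall each. The lists of PIKKs with TTT and R2TP, M-cell genes and the respiratory chain then had no call. With each library left out in turn, rvb2, the call of the PIKK list, was kept in 1 of 9 fits. The NuA4 gene vid21 was kept in none.

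Without WT replicate 1 the count of changed genes in tra1-AA was 398, and without tra1-AA replicate 2 it was 364; with library totals alone as the scaling, rises made up 59.7% of the calls against 49.9% with TMM. The titles of the WT and tra1D samples carry a re-analysis mark that the tra1-AA titles lack, so for the 313 genes called in tra1-AA alone the mark cannot be separated from the genotype, and since each genotype is a single strain, neither can strain background for any gene; the mark alone does not give the 468 calls that tra1D, which shares the mark of WT, had in the same direction.

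The comparison of tra1D with WT asks the same of cells without the gene, and both groups carry the re-analysis mark, so this comparison lies within it. ght5 rose 21.0-fold to 1742 ± 182 CPM (log2 fold change 4.39, SE 0.40, edgeR, BH-adjusted p = 4.32e-05). gal10 rose 5.76-fold from 4.18 ± 0.429 to 24.3 ± 6.71 CPM, pho842 rose 4.42-fold and zym1 rose 3.96-fold. Apart from tra1 itself, cnp3 fell 5.79-fold to 49.3 ± 10.7 CPM (log2 fold change -2.53, SE 0.12, edgeR, BH-adjusted p = 8.43e-08) and pfl3 fell 4.09-fold to 53.2 ± 7.63 CPM.

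In tra1D, 566 of 4913 genes changed (edgeR quasi-likelihood test, BH-adjusted p under 0.05), 254 up and 312 down, with a median absolute log2 fold change of 0.46, or 1.37-fold. Changes of at least 2-fold were found in 30 rises and 67 falls. The 8 largest rises were ght5, gal10, SPAC27D7.11c, pho842, zym1, gnr1, gcd1 and atd1, with log2 fold changes from 4.39 down to 1.89. The 8 largest falls were tra1, gdt1, SPAPB24D3.07c, SPBC23G7.10c, SPBPB10D8.02c, cnp3, str1 and nrg1, from -7.69 to -2.25. gdt1 had 148 counts in tra1D replicate 1 but 3 and 5 in replicates 2 and 3, and its log2 fold change moved from -3.50 to -7.16 without tra1D replicate 1 and, for gdt1, tra1D vs WT, to -2.90 without tra1D replicate 2. The call of str1, tra1D vs WT, was lost without tra1D replicate 2 (log2 fold change -2.105, edgeR, BH-adjusted p = 0.0641), and its log2 fold change was -1.51 without WT replicate 3.

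The list results of tra1D had the directions of those in tra1-AA where both passed. Of the 39 subtelomeric genes 15 fell, 3 rose and 21 did not pass, with 16 falls and 3 rises adjusted over the list alone (camera, BH-adjusted p = 0.000105; adjusted p = 0.483 with an estimated correlation). The list median was -0.68, and SPAC750.01 had 4 counts in tra1D, a WT to mutant ratio of 37.0 (95% counting interval 14.1 to 137). Of 16 genes in the drug and multidrug transporter list 3 fell, with 4 falls adjusted over the list alone (camera, BH-adjusted p = 0.00469, or 0.402 with an estimated correlation). The 3 were str3 at -2.39, which is also in the iron list, the arginase gene car1 at -1.15 and bfr1 at -0.64. Of 15 iron and siderophore uptake genes 5 fell, with 9 falls adjusted over the list alone (camera, BH-adjusted p = 0.0184; adjusted p = 0.402 with an estimated correlation), and this call was lost when no filter on low counts was used. Of 21 MBF and S phase genes 3 fell, also adjusted over the list alone (camera, BH-adjusted p = 0.0136; adjusted p = 0.568 with an estimated correlation): mik1 at -0.85, ams2 at -0.46 and ssb1 at -0.43. The MBF call was lost without WT replicate 2 (camera, BH-adjusted p = 0.0607).

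Growth-related lists in tra1D gave a similar picture of small shifts. Of 139 ribosomal protein genes 3 fell and 136 did not pass, with none called in edgeR when adjusted over the list alone, while 132 lay below 0 and the median was -0.16 (camera, BH-adjusted p = 1.73e-07; adjusted p = 0.753 with an estimated correlation). Of 68 ribosome biogenesis genes 3 fell and 1 rose, with 1 fall adjusted over the list alone (camera, BH-adjusted p = 0.000154; adjusted p = 0.713 with an estimated correlation). gar2 fell from 1896 ± 90.7 to 1305 ± 129 CPM, and the list's call was lost without WT replicate 3 (camera, BH-adjusted p = 0.1003). Of 59 amino acid biosynthesis genes 7 fell and 1 rose, with 9 falls and 1 rise adjusted over the list alone (camera, BH-adjusted p = 0.00118; adjusted p = 0.576 with an estimated correlation), with met17 at -1.26. Of 37 proteasome genes 3 rose and 1 fell, with 13 rises and 1 fall adjusted over the list alone (camera, BH-adjusted p = 0.00191; adjusted p = 0.483 with an estimated correlation), with rpn1301 at 0.44 and rpt4 at 0.30.

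Genes of mating rose in tra1D: 9 of 31 rose and 2 fell, with 13 rises and 3 falls adjusted over the list alone (camera, BH-adjusted p = 0.0116; adjusted p = 0.433 with an estimated correlation). ste11 rose 2.20-fold from 23.3 ± 3.51 to 51.1 ± 6.65 CPM, and map1 had a log2 fold change of 1.06. The list's call was lost with library totals alone as the scaling. Of 7 M-cell genes 3 rose (4 rises and 1 fall adjusted over the list alone), including the M-factor gene mfm2 at 1.06, whereas the list did not pass as a group (camera, BH-adjusted p = 0.0625) and none of 3 P-cell genes passed in edgeR.

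The following lists did not pass as groups in tra1D (camera, BH-adjusted p of 0.0851 and above). The SAGA list, in which tra1 fell, 2 genes rose and 16 did not pass (3 rises and 1 fall adjusted over the list alone), had a median of 0.16 and a mean of -0.28, which differ in sign because tra1 is a member. With tra1 left out, the list SAGA subunits, tra1D vs WT, passed upwards (camera, BH-adjusted p = 0.0110 with the preset correlation; not rerun with an estimated correlation). In the stress response list 7 of 23 genes rose and 7 fell (7 and 8 adjusted over the list alone), with hsp9 at 1.73 and gst2 at -2.10. In the Pap1 list 4 of 19 rose and 6 fell, also adjusted over the list alone, with tpx1 at 0.70 and obr1 at -2.08. Of 23 glucose-repressed and hexose transporter genes 3 rose and 2 fell (7 and 2 adjusted over the list alone), with inv1 at 1.72 and agl1 at -1.08, and of 24 nitrogen and amino acid transport genes 3 rose and 3 fell (3 and 4 adjusted over the list alone), with isp5 at 1.86. Of 19 chaperone genes 2 rose and 1 fell, also adjusted over the list alone, and the risers were sti1 at 0.44 and cdc37, another Hsp90 cochaperone gene, at 0.41, with a list median of 0.04 and a mean of -0.04. Of 14 flocculin and agglutinin genes 3 fell (4 adjusted over the list alone), led by pfl3.

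Single changes were found in tra1D in the NuA4, phosphate, histone and strain marker lists (1 gene each), while none of 11 PIKK, TTT and R2TP genes passed in edgeR. The gene called in the NuA4 list was arp42, which belongs to SWI/SNF and RSC. Copper and zinc genes and thiamine-regulated genes had 1 rise and 1 fall each, sterol genes 3 falls, and the respiratory chain 2 rises and 1 fall. For phosphate, camera's direction was down with a median of 0.01. Adjusted over the list alone, these gave 1 rise in the phosphate, histone, copper and zinc and thiamine lists, 1 fall in the thiamine list, 2 falls in copper and zinc and in strain markers, and 3 falls among sterol genes. The NuA4 and respiratory chain lists then had no call.

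Without tra1D replicate 2, WT replicate 1 or tra1D replicate 3 the count of changed genes in tra1D was 278, 281 or 323, and with library totals alone rises made up 64.9% of the calls against 44.9%. Strain background cannot be separated from the deletion, since each genotype is a single strain.

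**Figure D2:**
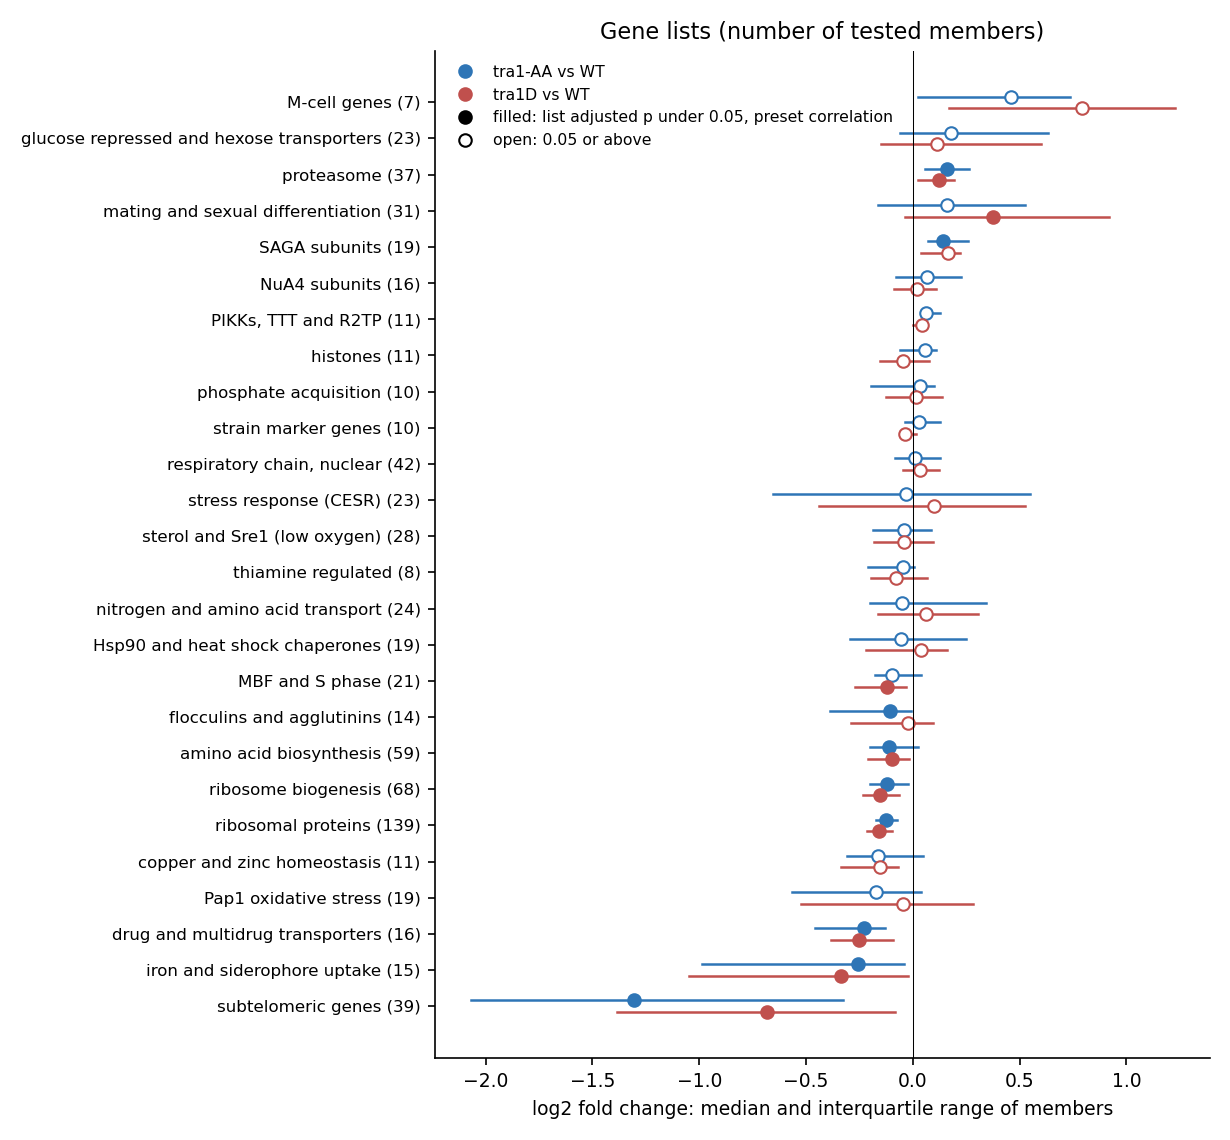
Median log2 fold change of each gene list reported here in tra1-AA and tra1D against WT, with bars for the interquartile range of its tested members (their number in brackets) and filled points where the camera adjusted p with the preset correlation was under 0.05. The subtelomeric list has the lowest median in both mutants, -1.31 and -0.68; with library totals alone the medians of the stress response and sterol lists in tra1-AA, and of the Pap1, flocculin, strain marker, histone and sterol lists in tra1D, change sign.

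The direct comparison of tra1-AA with tra1D asks whether the allele and the loss of the gene differ. It called 2 genes (edgeR quasi-likelihood test, BH-adjusted p under 0.05). The tra1D titles carry the re-analysis mark and the tra1-AA titles lack it. In this comparison the mark therefore cannot be separated from the genotype. tra1 was higher in tra1-AA by a log2 fold change of 7.44 (SE 0.20), and ubc7 (SPBP16F5.04), a ubiquitin-conjugating enzyme gene that lies directly beside tra1, was lower by a log2 fold change of -1.46 (SE 0.08). ubc7 had 61.0 ± 4.64 CPM in WT, 213 ± 12.8 CPM in tra1D and 77.6 ± 5.59 CPM in tra1-AA. At an unadjusted p under 0.05 the test counted 187 genes, limma-voom called 2 and DESeq2 called 4. The additional DESeq2 calls were mcs2, which encodes the cyclin H homologue and lies on the other side of tra1 (log2 fold change 1.39, DESeq2, BH-adjusted p = 4.38e-05; edgeR, BH-adjusted p = 0.141), and SPBC530.07c (-0.53, DESeq2, BH-adjusted p = 0.0255), both named here after their values were seen. Leaving out tra1D replicate 2 or tra1-AA replicate 2 gave 5 calls each. As groups, 9 of 27 lists differed between the mutants by camera with the preset correlation. Subtelomeric genes were lower in tra1-AA than in tra1D with a list median of -0.49 (camera, BH-adjusted p = 1.63e-12; adjusted p = 0.401 with an estimated correlation), the only list whose call stayed in all 9 fits that left out a library, though none of its members passed in edgeR. Whether the strand of the reads was used in counting is not given in the sources used here, so the part that overlapping and antisense reads have in the values of these neighbours stays open.

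Most genes called against WT differed little between the mutants. Of 879 genes called in either mutant, 745 had a 95% interval of the tra1-AA to tra1D difference that lay within 1.5-fold in both directions, and 827 within 2-fold. Both mutants shared 201 rises and 267 falls, and no gene was called in opposite directions by edgeR. Calls in tra1-AA alone numbered 313 and in tra1D alone 98. A call in only 1 mutant is not a difference between the mutants: of the 879 genes, the direct test called tra1 and ubc7. Not passing is not closeness either, as the largest absolute log2 difference among these genes that did not pass was 4.67. Fitted differences near that size include SPAC186.04c and SPAC186.06, which rest on few counts. These genes had no count in tra1-AA and 9 each in tra1D, of which 9 and 8 were in tra1D replicate 1. pho842, gal7 and SPAC27D7.11c were the shared rises with the smallest adjusted p, and cnp3, pfl3 and dea2 the shared falls.

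Across the 4913 genes, which are not independent replicates, the log2 fold changes of both mutants had a Pearson r of 0.852 and a Spearman rho of 0.861. Unchanged groups simulated against the same WT libraries gave a mean r of 0.50 (0.457 to 0.546 in 50 simulations), because both comparisons share their controls. The covariance was 0.138 against 0.0105 in the simulations, a difference of 0.127. The WT libraries cannot be split into parts of 2, so some of the excess may come from the shared controls.

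Both mutants lost the counts of neighbouring genes at an end of chromosome I. SPAC186.04c had 27, 21 and 19 counts in WT replicates 1 to 3, 9 in tra1D replicate 1 and none in the other mutant libraries. SPAC750.01 had 53, 50 and 52 counts in WT and at most 2 in any mutant library. The nearby flavohaemoglobin gene yhb1 kept 445, 496 and 474 counts in tra1D and 321, 412 and 312 in tra1-AA, against 1377, 1149 and 1326 in WT. Not all genes there fell: pfl9, between yhb1 and SPAC186.04c, had 70, 58 and 81 counts in WT and 103, 123 and 143 in tra1D. In tra1-AA replicates 1 to 3 it had 19, 118 and 13.

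**Figure D3:**
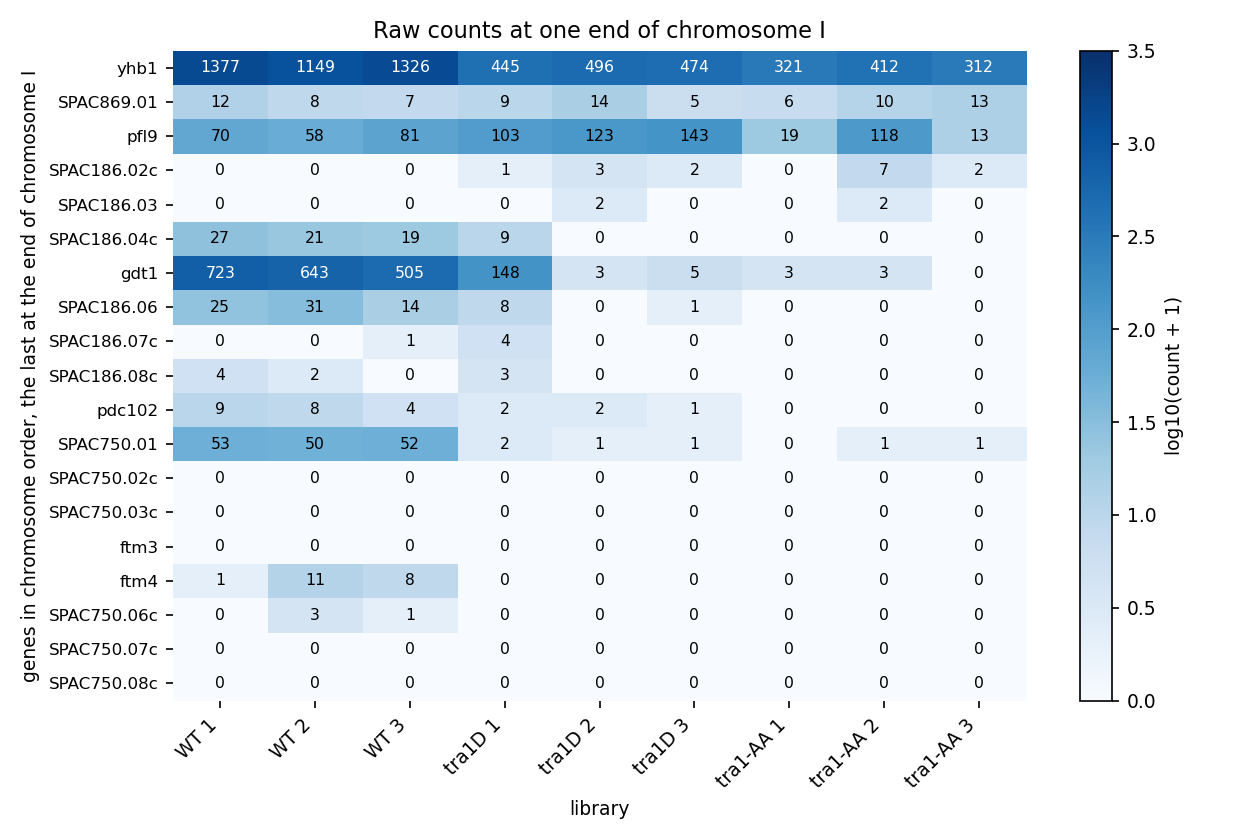
Raw counts per library of neighbouring genes at an end of chromosome I, from yhb1 to SPAC750.08c in chromosome order, coloured by log10 of the count plus 1, with WT, tra1D and tra1-AA libraries in columns. From SPAC186.04c on, counts seen in WT are near 0 in the mutants except in tra1D replicate 1, which kept 148 counts of gdt1.

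**Figure D4:**
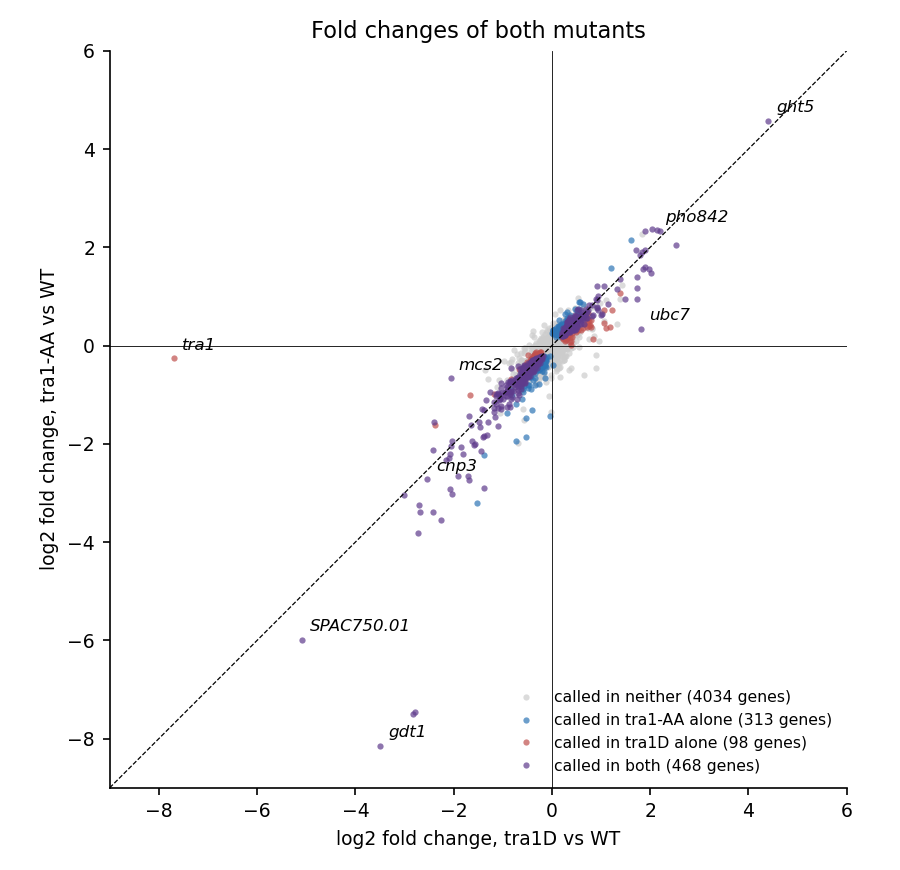
Log2 fold change of each tested gene in tra1D (horizontal axis) and tra1-AA (vertical axis) against WT, coloured by where the gene was called, with a dashed line of equal change. The 468 genes called in both lie on the same side of 0 in each mutant. Among the named points tra1, ubc7, mcs2 and gdt1 lie away from the line. gdt1, at -3.50 in tra1D and -8.14 in tra1-AA, did not pass between the mutants.

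The authors' deposited table for tra1-AA called 625 genes at an adjusted p under 0.05, 240 up and 385 down, of which 582 were also called by edgeR here, all in the same direction. The authors' deposited table for tra1D called 570, 205 up and 365 down, with 478 shared in the same direction. Log2 fold changes in the authors' deposited tables appear shrunken towards 0, with standard errors of at most 0.195 and 0.196: ght5 stands at 1.00 and 1.05 there, and tra1 in tra1D at -4.76. For gdt1 the authors' deposited tables give -4.68 in tra1-AA and -0.17 in tra1D.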

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

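The tests of wild-type RNA in tra1D replicate 1, of a local effect at tra1 and of tra1 reads on ubc7 and on mcs2 were chosen only after the result was seen.

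Other splits of each pair of groups number 10 with the real one, too few for a share under 0.05. The real split gave the most genes called for tra1-AA against WT (781, highest other 0, 1 of 10 splits as large) and for tra1D against WT (566, highest other 0, 1 of 10). For tra1-AA against tra1D it gave 2, the highest other gave 8, and 2 of 10 splits were as large.

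The test of the difference between the mutants brought the following results here. In all of them the re-analysis mark, which tra1D carries and tra1-AA lacks, cannot be separated from the genotype. In edgeR, tra1 differed by a log2 fold change of 7.44 and ubc7 by -1.46. The other results are camera adjusted p-values of lists, and all of these lists lost their call with an estimated correlation. SAGA subunits had 0.0136 (0.401 with an estimated correlation), lost without tra1 in the list and without tra1D replicate 1, tra1-AA replicate 2 or tra1-AA replicate 3 (up to 0.0694). The stress response list had 0.0428 (estimated 0.568), lost without tra1D replicate 3, tra1-AA replicate 1 or tra1-AA replicate 2 (up to 0.431). The Pap1 oxidative stress list had 0.0492 (estimated 0.568) and kept its call in 2 of 9 fits that left out a library (up to 0.545). Flocculins and agglutinins had 0.0492 (estimated 0.402), kept in 2 of 9 (up to 0.308). Mating and sexual differentiation had 0.00522 (estimated 0.402), lost without tra1D replicate 2 (0.0561). M-cell genes had 0.0428 (estimated 0.568), kept in 5 of 9 (up to 0.272). MBF and S phase genes had 0.0438 (estimated 0.568), kept in 4 of 9 (up to 0.586). Proteasome genes had 0.0455 (estimated 0.585), kept in 2 of 9 (up to 0.434). Subtelomeric genes had 1.63e-12 (estimated 0.401), with a median of -0.49, and kept the call in all 9 (highest 7.27e-06).

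Both direct neighbours of tra1 moved in tra1D, ubc7 up and mcs2 down. In tra1-AA vs WT they passed in the same directions by less: ubc7 at 0.35 and mcs2 at -0.67 (edgeR, BH-adjusted p = 0.016 and 0.0433). Of the 10 genes on each side, erf2 and SPBC3H7.05c also passed against WT in both mutants. Their log2 fold changes were -0.57 and -0.84 in tra1D, and -0.55 and -0.72 in tra1-AA. Among 18 genes further away the median absolute log2 fold change between the mutants was 0.09. None of them passed between the mutants in edgeR, while 1 direct neighbour passed. As the direct comparison had called only tra1 and ubc7 among all genes, this outcome was fixed beforehand, and a local effect of the changed locus and other causes cannot be told apart. Reads of tra1 counted on ubc7 are argued against, since ubc7 rose by a log2 fold change of 1.81 where tra1 was gone. For mcs2, the prediction took its whole fall in tra1D (-2.06) as lost tra1 reads, which would give -0.19 in tra1-AA. The low end of that prediction, -0.34, holds the error of tra1 in tra1-AA alone. The observed value was -0.67 (95% interval -1.11 to -0.23). These overlapping intervals mean that spill and a real fall cannot be told apart. How the deletion was built, for which the labels give no details, stays open and untested.

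The loss of counts around gdt1 was near complete in 5 mutant libraries and partial in tra1D replicate 1. A mix of wild-type RNA or reads into that library is argued against, because tra1 kept 0.772% of its WT level there (95% interval 0.251 to 1.80) and gdt1 24.9% (21.1 to 29.3). Reads shared with near-identical copies are argued against too, as 0% of the gdt1 coding sequence lies in a near-identical copy. SPAC186.04c and SPAC186.06 kept 42.3% and 36.3%, but SPAC750.01 kept 4.01% (0.485 to 14.5). A strain difference at this chromosome end, a silencing that varies between cultures, and an effect of tra1 itself stay open and untested, as each genotype is a single strain.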

How the results depend on the processing

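In tra1-AA against WT, 301 genes passed at an adjusted p of 0.01 and 82 the test against a log2 change of 0.5 (781 in the fit reported); the genes changed, tra1D vs WT, were 229 and 74 (566). With a library left out the counts ran from 364 (without tra1-AA replicate 2) to 845 (without tra1-AA replicate 1), and from 278 (without tra1D replicate 2) to 655 (without tra1-AA replicate 1). The stricter thresholds lower the counts by construction; for the libraries, the cause was not tested.

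Between the mutants DESeq2 called 4 genes, and counts ran from 2 to 5 with a library left out (5 without tra1D replicate 2); the cause was not tested. The tra1 transcript, tra1-AA vs WT, ran from -0.32 (without tra1-AA replicate 1) to -0.18 (without tra1-AA replicate 3). The agreement of tra1-AA and tra1D changes (Pearson r) was 0.766 with no filter, where genes with few counts enter, and 0.809 to 0.873 with a library left out. The number of list results called, 29 in the fit reported, was 0 with an estimated correlation and 21 to 28 with a library left out, newly called lists included.

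With the replicate number as a replicate block, 718, 514 and 3 genes were called, the third between the mutants being hsp9 (log2 fold change -0.80, edgeR, BH-adjusted p = 0.0034). The block also ended the calls of the Pap1, flocculin, M-cell and proteasome lists between the mutants. In the pairing check each WT library correlated best with the tra1-AA library of its own number (0.109, 0.357 and 0.215), a hint from the data and not the design, whereas same-number pairs with tra1D lay from -0.203 to -0.01.

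DESeq2 called 814 and 615 genes against WT, of which 721 and 524 were shared, all in the same direction; limma-voom called 781 and 533. Without WT replicate 3 and tra1D replicate 1 together, the counts were 638 and 415. Of 178 called results for named genes, 78 lost their call under some alternative, as did all 29 called list results. Depth limits the genes below the filter, 150 of which had a count. Camera was not rerun with DESeq2 or limma-voom.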

Other observations

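All tests in this part were written before their result was seen.

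Among tested genes in chromosome order, those that fell lay next to each other more often than random placement gives. In tra1-AA 62 adjacent pairs fell against 31.1 at random, and in tra1D 43 against 19.8, with a one-sided permutation p of 0.0001 in each, the smallest that 10000 placements allow. An excess of adjacent rises did not pass this test (36 pairs against 30.9, permutation p = 0.182, and 12 against 13.1, permutation p = 0.675). In both mutants the falls formed 21 runs of length 2, 4 of length 3 and 1 of length 4, the last made of SPAC186.04c, gdt1, SPAC186.06 and SPAC750.01. Untested genes were skipped, so a run can span them. In the longest run SPAC186.07c, SPAC186.08c and pdc102, all untested, lie between SPAC186.06 and SPAC750.01. Other runs were SPBPB21E7.09, SPBPB10D8.01 and SPBPB10D8.02c, ecl2, SPBP35G2.17 and txc1, and the pair of cnp3 and abp2, chosen after its values were seen.

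Chromosome ends alone are argued against as the source, since without the outermost genes the larger permutation p was 0.001 (39 pairs against 23.9 in tra1-AA; 32 against 15.9 in tra1D). Falls were also more frequent at the ends: 56 of 230 genes against 7.16% elsewhere in tra1-AA, odds ratio 4.18, and 39 of 230 against 5.83% elsewhere in tra1D, odds ratio 3.3 (Fisher's exact test, two-sided, p = 4.28e-15 and 7.66e-09). These tests treat genes as independent, and reads of overlapping neighbours, strain differences and an effect of tra1 on neighbouring genes stay open. Found and tested on the same data, this is a hypothesis.

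Ribosomal protein genes lay lower in both mutants by a small amount. Genes matched on coding length, GC content and level fell less. The list medians of -0.127 and -0.158 lay below those of matched lists (-0.052, 95% range -0.092 to -0.022, and -0.071, -0.093 to -0.045). The percentile was 0.01, the lowest that 10000 lists can give. Matched genes were drawn singly, while the members of the list move together (estimated correlation 0.826). The percentile therefore overstates the evidence and cannot decide whether these properties are the whole cause. The matches were close but not exact, with gaps of 0.35, 0.23 and 0.13 SD in level, length and GC content. Differences between libraries within a group fit, since the lowest WT library minus the highest mutant library was -0.099 in mean log2 CPM and the largest range within a group was 0.297. A difference in growth between the genotypes stays open and untested.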
